A study of Homo sapiens with 6 samples.

How the data were processed

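RNA was sequenced in 6 libraries, with 3 libraries labelled CFTR knockout and 3 labelled wild type. All were made from the human embryonic stem cell line H1 after directed differentiation. Per the labels' protocols, cell aggregates were harvested at day 3, left to attach for 2 days, and exposed to BMP4 at 10 pM between days 5 and 10. Retinoic acid at 1 μM followed for 2 days and the GSK3 inhibitor CHIR99021 at 6 μM for 4 days. RNA was taken at day 16 with a column kit, and libraries were made with an NEBNext Ultra RNA kit, also per the labels' protocols. Whether the libraries keep the strand is not given in the sources used here.

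The authors deposited FPKM values (fragments scaled by transcript length and by the library's mapped fragments) for 24338 genes in 1 table, with a column for each library. The submitters' processing notes name HISAT2 and the GRCh38 build. The tool that made the FPKM values, its version and the gene annotation are not given in the sources used here. Of the rows, 19974 carry Ensembl identifiers and 4364 carry names beginning with newGene, which give no position. All 19974 Ensembl identifiers matched GENCODE release 29, the GRCh38 annotation used here for coordinates, and 19922 of them are protein-coding there. A total of 2272 genes were at 0 in all 6 libraries.

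FPKM values hold no read counts, and the depth is unknown. Low values were searched for steps of a single read, using genes below 0.3 FPKM. The commonest ratio to knockout replicate 1 was shared by at most 9 genes of 960 in any of the 5 other libraries, so no relative depth could be read from them. An exact 0 in such a table can be a failed estimate, and a gene at 0 is described as listed at 0. Reads shared between near-identical genes can be split by the estimation in a way that is not given, which bears on histone, globin and XAGE genes.

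Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with a mean-variance trend and genotype as the sole term. Genes with a mean of at least 1 FPKM over the 6 libraries were kept, which left 12893 genes, 703 of them named newGene. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. A log2 difference is knockout minus wild type on this scale, which understates the change of low genes. CFTR lies under the filter, and its limma value comes from the fit of all 22066 genes above 0 in any library.

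The named genes followed a rule written before the data were examined. It took CFTR, then the 12 highest and 12 lowest log2 differences among genes past the threshold whose groups did not overlap. Symbols that are locus or clone numbers were passed over, as were XIST and Y-linked genes. From each of 32 gene lists it took up to 4 members past the threshold with the largest difference, or up to 2 with the highest mean where none passed. The 3 members of each marker list with the highest wild type mean were also taken. Genes named outside this rule are said to be so in the text, and some genes are not reported here.

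The lists were also fixed before the data were examined. They cover salivary, ectodermal, placodal, pluripotent, neural, neural crest, mesenchymal, trophoblast, endodermal, muscle, vascular and kidney cells. Others cover ion transport, signalling pathways, junctions, cell cycle, stress responses and RNA quality. Lists with at least 5 kept genes, 31 in all, were tested with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation. The directional test fry, which asks whether a list's genes move on balance one way without comparing them with other genes, was also run. Adjusted p-values for lists are Benjamini-Hochberg values over the 31 lists.

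The procedure was tested on simulated data for the comparison of knockout with wild type over 12893 genes. It recovered 14 of 67 genes changed 1.5-fold, 49 of 67 changed 2-fold and 64 of 66 changed 4-fold, with 9 false calls among 12693 unchanged genes. The changed genes were drawn from those with a mean log2(FPKM + 1) above 1.5, and were far fewer than the genes called in the real data. The recovered shares therefore do not cover lower genes and may differ from those in the real comparison. The 1 list that was moved was called, and none of 19 unmoved lists was. The simulated genes varied independently of each other, whereas the lists called in the real data had estimated correlations of 0.225 to 0.731. The simulation therefore cannot show how often camera at the preset correlation calls lists of correlated genes falsely. Alternatives covered the pseudocount, the filter, the scaling, the variance model, sample weights, the replicate number as a block and each library left out in turn. Figures were drawn with matplotlib 3.10.9.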

Results

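Gene expression was measured in cells taken at day 16 of a protocol meant to turn H1 embryonic stem cells into salivary gland epithelial progenitors. The comparison asks how cells in which CFTR, the chloride and bicarbonate channel mutated in cystic fibrosis, was knocked out differ from wild type cells. There were 3 libraries per group. Summed FPKM ran from 352255 to 393559 per library, and between 12209 and 13188 genes reached 1 FPKM. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. A single knockout code appears in the labels, and the clone and the genotype cannot be told apart.

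CFTR itself (ENSG00000001626, GRCh38 chromosome 7, 117465784 to 117715971, plus strand) was low in every library. The knockout libraries had 0.682, 0.821 and 1.37 FPKM and the wild type libraries 1.07, 1.29 and 0.344 FPKM. The means were 0.959 ± 0.366 in knockout and 0.903 ± 0.497 in wild type (SD, n = 3 each), with a log2 difference of 0.06 (SE 0.24). The exact two-sided permutation test gave p = 0.9, where 0.1 is the smallest p that 3 against 3 allows, and limma gave an adjusted p of 0.881. A frameshift can leave transcript levels as they were, and the transcript level therefore does not check the genotype labels.

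Wild type cells at day 16 had high levels of simple-epithelial keratins, with KRT8 at 1406 ± 151 FPKM, KRT18 at 953 ± 120 and KRT19 at 814 ± 118 (SD, n = 3). Matrix genes of mesenchyme were as high: COL3A1, a fibrillar collagen, stood at 2728 ± 1391 FPKM, SPARC at 1187 ± 504 and COL1A1 at 1068 ± 427. Genes of trophoblast and amnion, extraembryonic tissues that BMP4 can induce from pluripotent cells, were also present. CGA, the shared subunit of glycoprotein hormones, was at 472 ± 141 FPKM and the transcription factor HAND1 at 360 ± 4.09. Of the 33 acinar and mature duct genes on the list, 2 reached a wild type mean of 1 FPKM, and WFDC2, a secreted protease-inhibitor family member, was the highest at 36.5 ± 12.3. Of 27 salivary epithelial progenitor genes, 17 reached 1 FPKM.

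The knockout and wild type libraries separated along the first principal component, which held 75.0% of the variance, while the second held 11.2%. Pearson correlations across genes were 0.967 to 0.983 within groups and 0.870 to 0.952 between them. Knockout replicate 2 and wild type replicate 2 lay closest to each other across the groups, with r = 0.952. Knockout replicate 3 stood apart in its mitochondrially encoded transcripts, which made up 4.92% of summed FPKM against 8.75% to 11.9% in the 5 other libraries. Wild type replicate 2 had 132 FPKM of AFP, the alpha-fetoprotein of fetal liver and yolk sac, against 28.1 and 15.1 in the other wild type libraries.

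**Figure D1:**
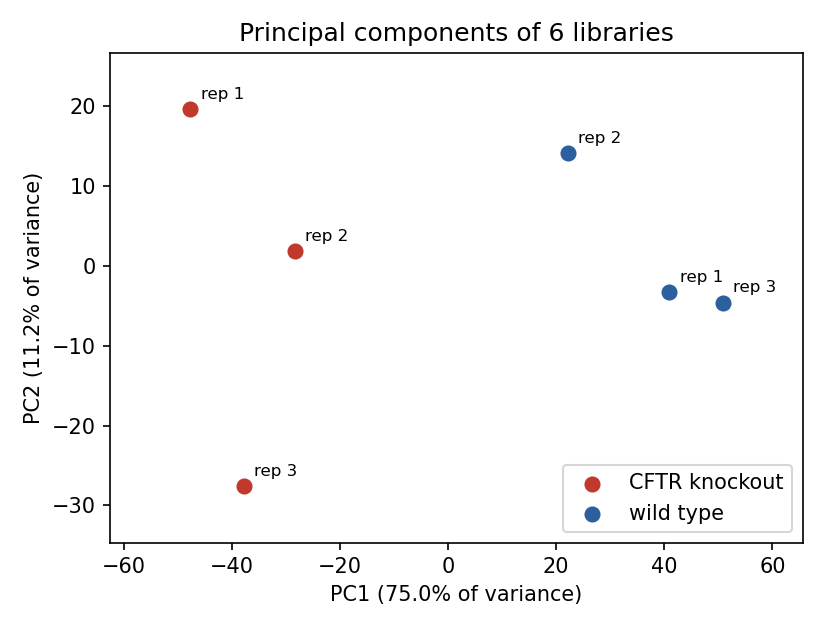
Principal components of log2(FPKM + 1) over 12893 genes, with PC1 (75.0% of variance) on the horizontal axis, PC2 (11.2%) on the vertical axis and a point for each of the 6 libraries, coloured by group. The knockout libraries lie at negative and the wild type libraries at positive PC1, and the replicate 2 libraries are the innermost of each group.

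In the knockout libraries 32 of 38 tested epithelial junction genes, 24 of 26 trophoblast and amnion genes and 17 of 19 oral and surface ectoderm genes fell, and 21 of 40 mesenchyme genes rose. Camera passed these 4 lists at the preset correlation, and none of them with an estimated correlation (adjusted p = 0.553 with an estimated correlation for each). EPCAM, an epithelial adhesion molecule, was at 14.7 ± 7.52 FPKM in knockout and 114 ± 22.7 in wild type, a log2 difference of -2.99 (SE 0.36, limma adjusted p = 0.00102, n = 3 each). LOX, an enzyme that crosslinks collagen, was at 59.9 ± 24.7 FPKM in knockout and 8.51 ± 7.52 in wild type, a log2 difference of 2.89 (SE 0.49, adjusted p = 0.00368), or 3.50 without wild type replicate 2. Over all tested genes, 3986 of 12893 passed the threshold, 1061 higher and 2925 lower in knockout, and 1366 of them differed at least 2-fold. The groups did not overlap for 6181 genes, where chance gives 10% of those tested.

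The share of lower genes depended on the scaling between libraries. It was 73.4% as deposited, where the median gene lay at a log2 difference of -0.15, against 53.9% with median-of-ratios scaling and 47.4% with quantile normalization, which moved that median to 0.00 and 0.04. Leaving out wild type replicate 3 left 2363 genes, 593 higher and 1770 lower, and leaving out wild type replicate 1 left 2459, 641 higher and 1818 lower.

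The highest log2 difference among the named genes was that of GLIPR1 (ENSG00000139278, chromosome 12, 75480680 to 75503853), at 87.3 ± 32.1 FPKM in knockout and 6.98 ± 4.03 in wild type, a log2 difference of 3.53 (SE 0.37, adjusted p = 0.000796). Among the 12 highest, ITGA11, a collagen-binding integrin, rose by 2.83, OGN, a small proteoglycan, by 2.68, and MGP, matrix Gla protein, by 2.53 on the log2 scale. SST, the hormone somatostatin, was at 2267 ± 1047 FPKM against 349 ± 376, SLC18A3, the vesicular acetylcholine transporter, at 36.5 ± 13.7 against 4.27 ± 1.63, and NEFL, a neurofilament subunit, at 23.4 ± 6.54 against 3.15 ± 1.67. The wild type values of SST were 158, 782 and 106 FPKM, and without wild type replicate 2 its log2 difference of 3.16 became 4.02 and that of MGP 3.17. In the fixed neural list 3 of 12 genes fell and 1 rose. CLDN11 rose by 3.03 and TFPI2, a protease inhibitor, by 2.74. DLK1, a growth regulator of fetal tissue, had a log2 difference of 2.65 and NEFM, another neurofilament subunit, of 2.75. Without wild type replicate 2 these became 3.78 and 3.73, and without wild type replicate 3 1.98 and 2.06. DLK1 stood at 1302 FPKM in wild type replicate 2 against 143 and 106 in the other wild type libraries. The limma adjusted p of DLK1 was 0.0362 and exceeded 0.05 when any library but wild type replicate 2 was left out, reaching 0.137 without wild type replicate 1. That of NEFM was 0.0274, and 0.107 without wild type replicate 1, 0.0882 without wild type replicate 3, 0.0611 without knockout replicate 1 and 0.0515 without knockout replicate 2.

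Among the lowest was MUC15 (ENSG00000169550, chromosome 11, 26559033 to 26572233), a membrane mucin, at 0.884 ± 0.586 FPKM in knockout and 31.1 ± 12.1 in wild type, a log2 difference of -4.07 (SE 0.32, adjusted p = 0.000684). LIN28A, an RNA-binding protein of stem cells, was at 3.59 ± 2.75 FPKM against 68.6 ± 30.7. CRH, corticotropin-releasing hormone, was at 0.587 ± 0.459 against 20.01 ± 6.25. PTN, the growth factor pleiotrophin, was at 28.1 ± 14.9 against 380 ± 110, and ID1, a target of BMP signalling, at 23.6 ± 13.4 against 263 ± 68.8. The log2 differences were -4.04 for the chemokine receptor CCR7, -4.00 for the neuropeptide NTS and -3.60 for the interferon-induced IFI6. They were -3.57 for the TNF receptor TNFRSF1B, -3.48 for the pigment-cell protein PMEL and -3.41 for the keratin KRT23. That of NTS was -4.88 without wild type replicate 2 and -3.23 without wild type replicate 3. MRGPRX1 was listed at 0 in knockout replicate 1, with 1.29 and 0.247 FPKM in the other knockout libraries and 12.6 to 31.1 in wild type.

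**Figure D2:**
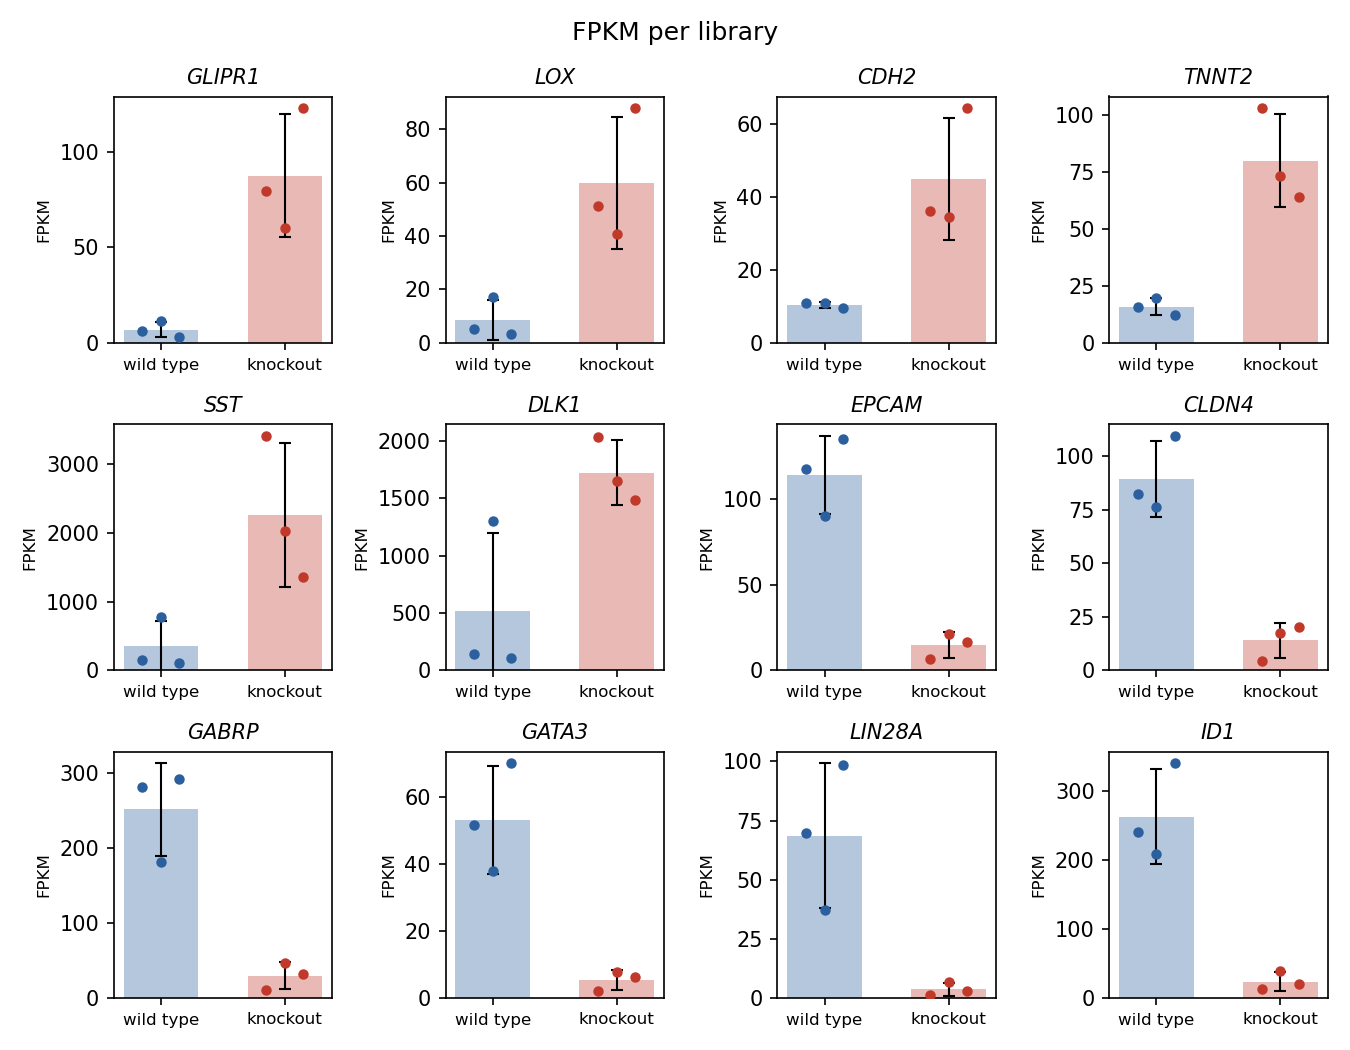
FPKM of 12 named genes in the 3 wild type and 3 knockout libraries, with points for libraries, bars for group means and error bars for the SD (drawn from 0 where the mean minus the SD is negative). EPCAM stands at 114 in wild type and 14.7 in knockout, and LOX at 8.51 and 59.9.

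In the epithelial junction and adhesion list, 32 of 38 tested members fell, 1 rose and 5 did not pass, with a median log2 difference of -1.56 (adjusted over the list alone, 35 fell and 1 rose). CLDN3, a tight junction protein, was at 0.784 ± 0.499 FPKM in knockout and 15.4 ± 4.43 in wild type. CLDN4, of the same family, was at 13.97 ± 8.33 against 89.2 ± 17.7 (log2 difference -2.80, and -2.18 without knockout replicate 1), and RAB25, a vesicle-transport GTPase of epithelia, at 4.32 ± 2.82 against 38.8 ± 12.6. Camera gave an adjusted p of 4.67e-09. With an estimated correlation the adjusted p = 0.553, the value that also holds for the 6 other lists past the threshold, so that none of the 7 calls is kept. Without knockout replicate 1 or wild type replicate 2, 11 lists passed with the preset correlation. The member that rose, named after its value was seen, was the desmosomal cadherin DSC3.

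In the trophoblast and amnion list, 24 of 26 members fell and 1 rose, with a median of -2.43 (adjusted over the list alone, 24 and 1; camera adjusted p = 3.38e-08, and adjusted p = 0.553 with an estimated correlation). CYP19A1, the aromatase of estrogen synthesis, was at 2.92 ± 1.93 FPKM in knockout and 34.2 ± 12.3 in wild type. GABRP, a GABA receptor subunit, was at 29.9 ± 18.1 against 252 ± 61.7, and the transcription factor GATA2 at 4.54 ± 2.83 against 45.4 ± 14.3. The exception was IGFBP3, at 1424 ± 251 FPKM in knockout and 830 ± 222 in wild type, whose limma adjusted p of 0.0286 became 0.107 without wild type replicate 1, 0.106 without wild type replicate 3, 0.0723 without knockout replicate 1 and 0.0708 without knockout replicate 2. In the oral and surface ectoderm list, 17 of 19 members fell and 1 rose, with a median of -1.69 (adjusted over the list alone, 17 and 1; camera adjusted p = 2.69e-06, and adjusted p = 0.553 with an estimated correlation). GATA3 was at 5.36 ± 2.85 FPKM against 53.1 ± 16.1, TFAP2C at 2.14 ± 1.37 against 22.4 ± 7.50, and DLX5 at 2.61 ± 2.08 against 32.4 ± 8.13, all of them transcription factors. The 2 lists share 4 tested genes, GATA3 and TFAP2C among them, and DLX5 is also in the cranial placode list.

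In the pluripotency list, 8 of 9 members fell and none rose, with a median of -2.05 (adjusted over the list alone, 9 fell; camera adjusted p = 0.000255, and adjusted p = 0.553 with an estimated correlation). L1TD1 was at 2.49 ± 1.31 FPKM in knockout and 29.3 ± 9.21 in wild type, and SALL4, a stem cell transcription factor, at 2.36 ± 0.927 against 14.1 ± 3.16. POU5F1, which encodes OCT4, was at 8.97, 2.92 and 28.5 FPKM in the wild type libraries, at 0.0606 and 0.0573 in knockout replicates 1 and 2, and listed at 0 in replicate 3. In the cranial placode list, 5 of 7 members fell and none rose, with a median of -1.61 (adjusted over the list alone, 6 fell; camera adjusted p = 0.00569, and adjusted p = 0.553 with an estimated correlation). EYA1 was at 1.06 ± 0.745 FPKM against 8.76 ± 1.69 and FOXI3 at 0.303 ± 0.163 against 5.03 ± 1.90. The placode call ended without the filter on low genes, with an adjusted p of 0.149.

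In the mesenchyme and matrix list, 21 of 40 members rose, 3 fell and 16 did not pass, with a median of 0.73 (adjusted over the list alone, 25 and 5; camera adjusted p = 2.42e-08, and adjusted p = 0.553 with an estimated correlation). COL1A1 was at 2604 ± 237 FPKM in knockout and 1068 ± 427 in wild type, and CDH2, the N-cadherin of mesenchyme and neurons, at 44.99 ± 16.8 against 10.5 ± 0.824. Against the list's direction, the transcription factors SNAI1 and PRRX1 fell, SNAI1 from 13.4 ± 3.74 FPKM in wild type to 1.81 ± 0.765 and PRRX1 from 7.05 ± 3.06 to 0.874 ± 0.208. The other member that fell, named after its value was seen, was the fibrillin FBN2. The replication-dependent histone list, a sign of how RNA was selected since most of these transcripts lack a poly(A) tail, had 6 of 10 members higher and 1 lower (adjusted over the list alone, 7 and 1; camera adjusted p = 0.000762, and adjusted p = 0.553 with an estimated correlation). HIST1H2BK was at 85.3 ± 8.15 FPKM against 39.4 ± 10.9, while H1F0, a linker histone made outside DNA replication, was at 34.8 ± 3.22 against 68.6 ± 7.27. That call ended when genes with a mean under 5 FPKM were left out, with an adjusted p of 0.179.

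**Figure D3:**
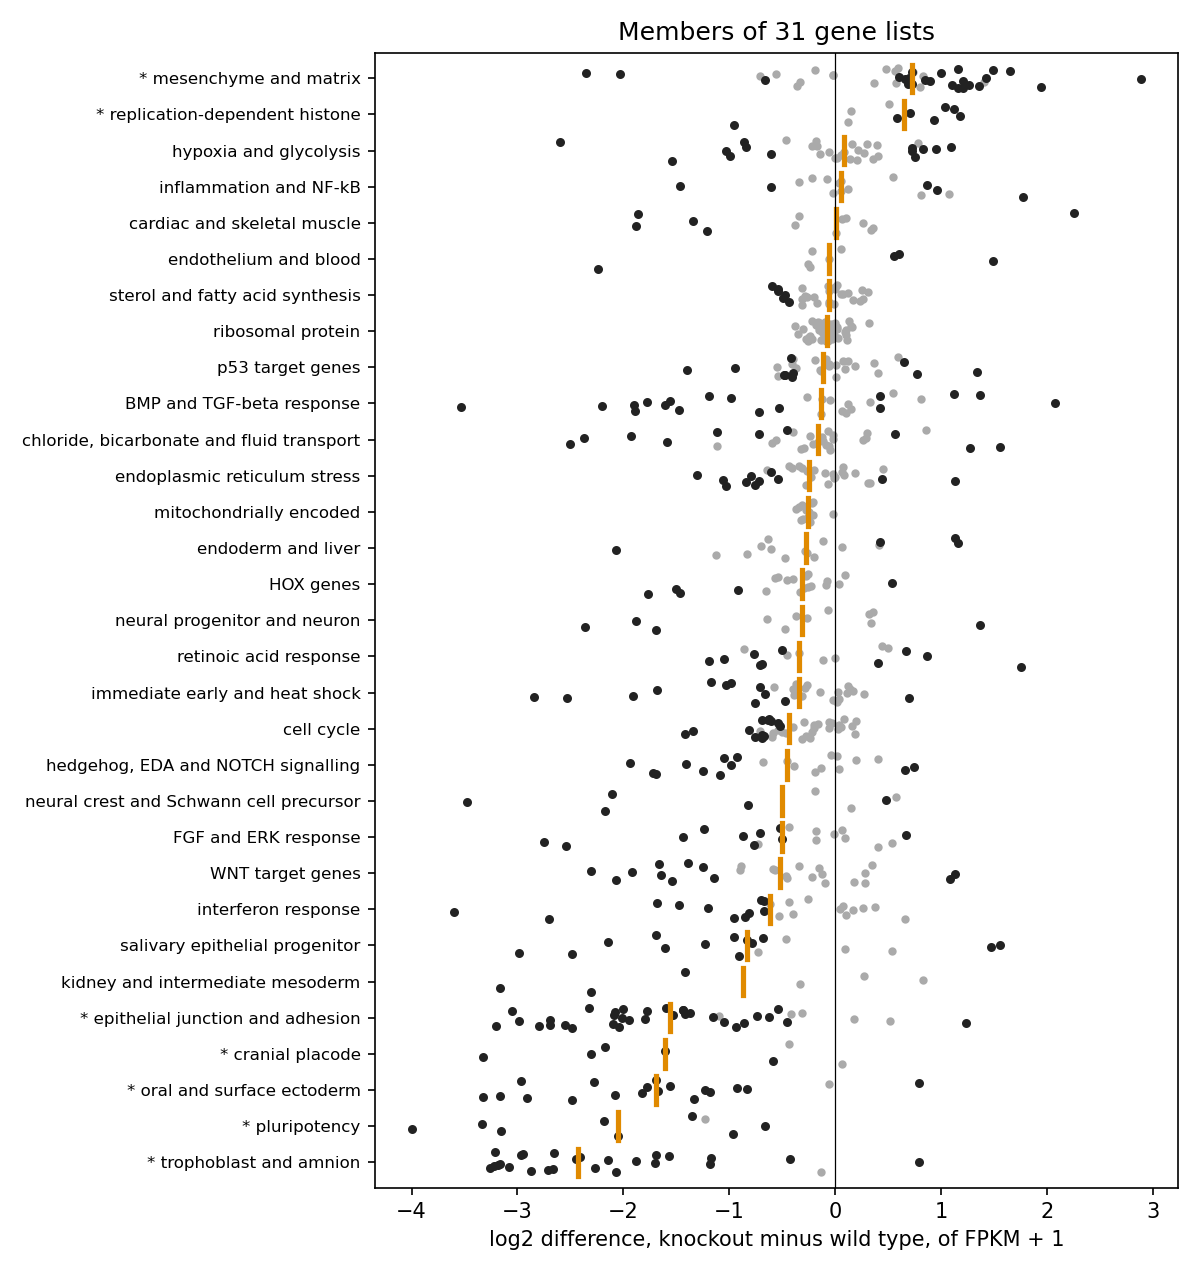
Log2 differences, knockout minus wild type, of the tested members of 31 gene lists, with a point for each gene (dark where its adjusted p is under 0.05), an orange bar for each list's median and an asterisk where camera's adjusted p is under 0.05. The medians run from -2.43 for trophoblast and amnion to 0.73 for mesenchyme and matrix. The asterisks hold for camera at the preset correlation, and no list passed with an estimated correlation.

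The lists tied most closely to the salivary gland and to CFTR did not pass with camera, while fry passed both as lower, the salivary epithelial progenitor list with an adjusted p of 0.0301 and the chloride, bicarbonate and fluid transport list with 0.0334. With an estimated correlation camera gave these adjusted p = 0.781 and 0.975. Fry does not compare a list with other genes and was run on the values as deposited alone. The transport list's median of -0.17 lay near that of all tested genes, -0.15, so its fry call does not set it apart from them. Of 17 salivary epithelial progenitor genes, 11 fell and 2 rose, with a median of -0.83 (adjusted over the list alone, 12 and 2; camera adjusted p = 0.086). CDH1, the E-cadherin of epithelia, was at 17.3 ± 8.18 FPKM in knockout and 94.7 ± 21.2 in wild type, KRT7 at 54.7 ± 29.5 against 217 ± 46.5 and TP63, a regulator of stratified epithelium, at 0.296 ± 0.220 against 3.18 ± 0.571. The 2 that rose, named after their values were seen, were the receptor KIT, at 7.85 ± 1.81 FPKM against 1.99 ± 0.478, and ITGA6, an integrin, at 90.7 ± 17.9 against 32.9 ± 10.9. That list passed without knockout replicate 1 (adjusted p = 0.0335) and without knockout replicate 2 (adjusted p = 0.0447), and with median-of-ratios scaling (0.0196), quantile normalization (0.0122) or a mean of at least 5 FPKM (0.0289). Over all 6 libraries it had an adjusted p = 0.781 with an estimated correlation. WFDC2 was the 1 tested acinar and mature duct gene, at 4.28 ± 2.77 FPKM in knockout and 36.5 ± 12.3 in wild type. Of 31 chloride, bicarbonate and fluid transport genes, 7 fell, 3 rose and 21 did not pass (adjusted over the list alone, 8 and 4; camera adjusted p = 0.938). BEST1, a calcium-activated anion channel, was at 1.95 ± 1.79 FPKM against 15.2 ± 7.25, KCNN4, a calcium-activated potassium channel, at 2.88 ± 2.13 against 16.8 ± 4.67 (log2 difference -2.37, and -1.78 without knockout replicate 1), and SCNN1A, a subunit of the epithelial sodium channel, at 0.565 ± 0.505 against 4.93 ± 1.77. AQP1, a water channel named after its value was seen, was at 285 ± 29.8 FPKM against 124 ± 55.6.

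Among signalling lists, genes changed in both directions and none passed with camera. Fry passed as lower the BMP and TGF-beta (adjusted p = 0.0256), WNT (0.0429), retinoic acid (0.0301) and hedgehog, EDA and NOTCH (0.0119) lists. With an estimated correlation camera gave these adjusted p = 0.975, 0.886, 0.975 and 0.781. The median of the BMP and TGF-beta list was -0.13, near that of all tested genes, -0.15. Of 28 BMP and TGF-beta genes, 12 fell and 5 rose (adjusted over the list alone, the same counts; camera adjusted p = 0.812). ID2 was at 19.1 ± 6.71 FPKM against 90.6 ± 28.1 and ID4 at 2.79 ± 0.156 against 13.4 ± 3.49, while LTBP1, a latent TGF-beta binding protein, was at 79.3 ± 17.2 against 18.5 ± 6.87. Of 26 WNT target genes, 9 fell and 2 rose (12 and 4 adjusted over the list alone; camera adjusted p = 0.244). RNF43, a WNT feedback inhibitor, was at 0.556 ± 0.163 FPKM against 6.89 ± 2.22 and NOTUM, another, at 1.42 ± 0.534 against 7.97 ± 0.613. Of 19 FGF and ERK genes, 9 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.263), with DUSP5 at 3.05 ± 2.04 FPKM against 20.4 ± 5.68. Of 17 retinoic acid genes, 6 fell and 4 rose (7 and 5 adjusted over the list alone; camera adjusted p = 0.812). CRABP1, a retinoic acid binding protein, was at 124 ± 59.2 FPKM against 35.1 ± 13.004. Of 21 hedgehog, EDA and NOTCH genes, 9 fell and 2 rose (10 and 2 adjusted over the list alone; camera adjusted p = 0.308), with HEY2 at 0.841 ± 0.592 FPKM against 5.95 ± 2.00. Of 20 HOX genes, 4 fell and 1 rose (the same adjusted over the list alone; camera adjusted p = 0.282).

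Lists of markers of other cell types did not pass with camera. Fry passed as lower the kidney list (median -0.87, adjusted p = 0.0119), the neural crest list (median -0.50, adjusted p = 0.0119) and the neural list (median -0.32, adjusted p = 0.0301), and as higher the endothelial list (median -0.05, adjusted p = 0.02). With an estimated correlation camera gave these adjusted p = 0.781, 0.786, 0.975 and 0.553. Of 12 neural genes, 3 fell and 1 rose (camera adjusted p = 0.882), and of 8 neural crest genes 4 fell and 1 rose (adjusted p = 0.517). ISL1 was at 6.33 ± 3.50 FPKM against 23.6 ± 0.812 and ERBB3 at 1.84 ± 0.862 against 11.8 ± 3.77. Of 13 muscle genes, 4 fell and 1 rose (adjusted p = 0.882). TNNT2, cardiac troponin T, was at 80.2 ± 20.4 FPKM against 15.9 ± 3.85, whereas TNNT1, the slow skeletal form, was at 6.92 ± 1.53 against 27.6 ± 4.59. Of 9 endothelial and blood genes, 3 rose and 1 fell (adjusted p = 0.225), with FLT1, a VEGF receptor, at 67.7 ± 16.1 FPKM against 23.0 ± 1.40 and CDH5, the VE-cadherin of vessels, at 1.15 ± 0.780 against 9.06 ± 3.56. Of 16 endoderm and liver genes, 3 rose and 1 fell (adjusted p = 0.534), with GATA4 at 22.9 ± 3.01 FPKM against 9.72 ± 1.84. Without wild type replicate 2, which holds the high AFP, that list passed as higher in knockout (adjusted p = 0.0017). Over all 6 libraries it had an adjusted p = 0.975 with an estimated correlation. Of 6 kidney genes, 3 fell (adjusted p = 0.517). Adjusted over the list alone, the calls in these lists were the same except that a second neural crest gene and 1 kidney gene rose. The mean, median or camera direction differed in sign for the muscle, endothelial, endoderm, retinoic acid, hypoxia, p53, sterol and ribosomal lists. Under at least 1 other scaling the median changed sign for the endothelial, ribosomal, BMP and TGF-beta, p53 and sterol lists.

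Of 23 interferon response genes, 11 fell and none rose, with a median of -0.61 (13 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.078). Fry passed it as lower (adjusted p = 0.0119), as it did the immediate early and heat shock list (adjusted p = 0.0119), where camera with an estimated correlation gave adjusted p = 0.553 and 0.781. BST2 was at 7.22 ± 1.36 FPKM against 54.4 ± 21.4 and ISG15 at 7.23 ± 2.89 against 24.7 ± 6.87. This list passed without knockout replicate 1 (adjusted p = 0.0446), wild type replicate 1 (adjusted p = 0.0272) or wild type replicate 3 (adjusted p = 0.0353), and with median-of-ratios scaling (0.0247) or quantile normalization (0.0267). With all 6 libraries its adjusted p = 0.553 with an estimated correlation. Of 38 cell cycle genes, 13 fell and none rose (14 adjusted over the list alone; camera adjusted p = 0.121). CCNE1, cyclin E1, was at 13.5 ± 1.84 FPKM against 38.3 ± 9.88 and CDK2 at 15.2 ± 3.04 against 39.7 ± 5.39. Without wild type replicate 2 the cell cycle list passed (adjusted p = 0.000118), and without knockout replicate 2 it did so with an adjusted p of 0.043, as with quantile normalization (0.0174). Its genes had an estimated correlation of 0.849 over all 6 libraries, where the list had an adjusted p = 0.975 with an estimated correlation. Of 30 immediate early and heat shock genes, which respond to handling, 11 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 0.171, 0.0327 without knockout replicate 3, 0.0204 with quantile normalization, and adjusted p = 0.781 with an estimated correlation over all 6 libraries). EGR1 was at 7.29 ± 2.33 FPKM against 45.9 ± 5.67, FOSB at 1.49 ± 0.585 against 8.17 ± 0.652 and IER2 at 14.4 ± 3.63 against 48.0 ± 5.31.

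Of 33 hypoxia and glycolysis genes, 7 fell and 6 rose (7 and 7 adjusted over the list alone; camera adjusted p = 0.078), with SLC2A3, a glucose transporter, at 78.3 ± 40.1 FPKM against 435 ± 108 and PFKFB3 at 24.2 ± 1.77 against 10.9 ± 1.51. It passed as higher without knockout replicate 1 (adjusted p = 0.0414) or wild type replicate 3 (adjusted p = 0.0344), with an adjusted p = 0.781 with an estimated correlation over all 6 libraries. Of 16 inflammation and NF-kB genes, 3 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.078), with BIRC3 at 6.73 ± 0.825 FPKM against 1.27 ± 0.391 and NFKBIA at 9.35 ± 2.22 against 27.3 ± 4.28. It passed without knockout replicate 1 (adjusted p = 0.0289) or wild type replicate 2 (adjusted p = 0.0304), with an adjusted p = 0.553 with an estimated correlation over all 6 libraries. Of 32 endoplasmic reticulum stress genes, 9 fell and 2 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.812), with HERPUD1 at 15.9 ± 0.382 FPKM against 42.0 ± 12.1 and CREB3L1 at 178 ± 15.04 against 81.9 ± 22.3. Of 30 p53 target genes, 7 fell and 3 rose (the same adjusted over the list alone; camera adjusted p = 0.812), with GDF15 at 27.8 ± 9.19 FPKM against 73.4 ± 19.2 and FAS at 5.63 ± 3.11 against 1.48 ± 0.425. Of 29 sterol and fatty acid synthesis genes, 6 fell (3 adjusted over the list alone; camera adjusted p = 0.938), with SREBF2 at 36.6 ± 1.44 FPKM against 55.9 ± 1.51. None of 53 ribosomal protein genes passed with limma (camera adjusted p = 0.613, and 0.0416 as higher without wild type replicate 2). None of 13 mitochondrially encoded genes passed (camera adjusted p = 0.938), but without knockout replicate 3 the list's median turned from -0.26 to 0.17 (adjusted p = 0.0183). Over all 6 libraries the ribosomal and mitochondrial lists each had an adjusted p = 0.975 with an estimated correlation.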

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

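CFTR stayed short of the threshold in all 18 alternatives, but its log2 difference turned to -0.08 without knockout replicate 3 and -0.17 without wild type replicate 3. The separation of the libraries kept its direction in both of its alternatives. Of 152 named genes past the threshold, 119 kept their call with each library left out in turn and 33 lost it in at least 1 case. Most named genes were picked for large differences, so this does not describe all calls. Of all 3986 genes called, 2341 were also called without wild type replicate 3, the fewest, and 3572 without wild type replicate 2, the most. With quantile normalization 2865 were. In the alternatives that tested them, 131 of 165 named genes and 6 of 31 lists never changed their call. Not every alternative tested each of them: with a mean of at least 5 FPKM, 132 of the named genes were left.

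The count of changed genes fell from 3986 to 2574 with a mean FPKM of at least 5, where 8747 genes were tested. In the same setting 1769 were lower and 757 differed at least 2-fold. Genes higher in knockout numbered 1763 with median-of-ratios scaling and 2027 with quantile normalization, and 1824 were lower with quantile normalization. The cause was not tested beyond the shift of the median gene. With sample weights the median gene stayed at -0.15, and 5644 genes passed, 1596 higher and 4048 lower. Leaving out 1 library gave 2363 to 4224 changed genes, 593 to 1127 higher, 1770 to 3097 lower, 1114 to 1642 at least 2-fold, and 8 to 11 lists, all with fewer samples. Lists past the threshold numbered 11 with quantile normalization, 0 with an estimated correlation and 19 with fry. The retinoic acid list, not past the threshold with camera (adjusted p = 0.812), passed as lower by fry (median -0.34, adjusted p = 0.0301), and the mitochondrial list ran from -0.49 without knockout replicate 1 to 0.17 without knockout replicate 3. The causes were not tested.

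With the replicate number as a replicate block, 3200 genes passed, 834 higher, 2366 lower and 1375 at least 2-fold, and CFTR stayed at 0.06. Camera at the preset correlation then passed 7 lists, whereas without the block an estimated correlation passed none. Same-numbered libraries deviated from their group means with correlations of -0.11, -0.17 and 0.13, and not every library correlated best with its own number. Libraries with different numbers ranged from -0.28 to 0.31. Deviations within a group of 3 cancel for each gene, which ties these values to each other. The same-numbered values were not raised as a set, but with 3 libraries per group they cannot exclude that a shared number marks a shared batch. Chosen after seeing the data, leaving out newGene rows gave 3770 genes, leaving out mitochondrial genes 3716, and leaving out knockout replicate 3 with wild type replicate 2 gave 4263. DESeq2 was not run because the values are not counts, and CFTR has no value under the filter of 5 FPKM. Depth is unknown, and no counting error can be given.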

Other observations

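The genes, families and tests in this part were chosen after the results were seen, except the test of nuclear respiratory chain genes. Counted by cluster, of 6 HOXA genes 4 fell, with a median log2 difference of -1.19, while of 8 HOXB genes none fell and 1 rose, and of 6 HOXC genes none passed. The HOXA median was -0.83 with quantile normalization, -1.08 with median-of-ratios scaling and -1.49 after rescaling to TPM. The limma adjusted p-values of HOXA9 and HOXA10 rose to 0.0644 and 0.062 without wild type replicate 1, and to 0.056 and 0.0614 without wild type replicate 3. That of HOXA3 was 0.0637 without wild type replicate 3, 0.0513 without knockout replicate 1, 0.0589 without knockout replicate 3 and 0.178 with quantile normalization, where its log2 difference went from -0.92 to -0.50. That of HOXB7, the HOXB gene that rose, was 0.0665 without knockout replicate 2, 0.063 without wild type replicate 1 and 0.061 without wild type replicate 3. A difference between the clusters was not tested.

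Both genes of the cholinergic locus were higher in knockout: SLC18A3 by 2.81 and CHAT, choline acetyltransferase, by 1.83 on the log2 scale, CHAT at 4.16 ± 1.24 FPKM against 0.429 ± 0.105. SLC18A3 (chromosome 10, 49610301 to 49612720) lies within CHAT (49609095 to 49665104), so reads of the 2 genes may not be separable, and CHAT kept its sign with each scaling. Of 133 families of genes sharing a symbol root, 3 passed with camera, and none with an estimated correlation (adjusted p = 0.996). Of 24 SEC genes, many of them parts of the secretory pathway, 7 rose and 1 fell, with a median of 0.22 (adjusted p = 0.011, and 0.0616 with quantile normalization). The others were 17 HIST genes, of which 7 rose and 1 fell, with a median of 0.50 (adjusted p = 0.0166), and 14 GALNT genes, of which 5 rose and 3 fell, with a median of 0.42 (adjusted p = 0.0383). The HIST family shares members such as HIST1H2BK with the replication-dependent histone list, so its call is not separate from that list's. All 3 medians stayed above 0 under each scaling, but the calls of HIST and GALNT were lost with median-of-ratios scaling (0.0703 and 0.0922) and quantile normalization (0.0616 and 0.165), and that of GALNT also after rescaling to TPM (0.0555).

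Of the 10 splits of the 6 libraries into groups of 3, 1, the real one, gave as many as 3986 genes, and the highest of the others gave 0. These 10 splits are too few for a share under 0.05. Each split other than the real one mixes knockout and wild type libraries in both groups of 3. The difference between knockout and wild type then adds to the spread within groups, which lowers the count.

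The lower epithelial and higher mesenchyme lists in knockout were weighed against 3 explanations. Library scaling is argued against, since the epithelial median stayed at -1.42 or lower and the mesenchyme median at 0.749 or higher under 4 scalings. Both lists kept their camera calls at the preset correlation (without rescaling, adjusted p = 0.553 for each with an estimated correlation). Camera compares a list with other genes, so a shift of all genes alike would hardly change these calls, and they add no support. A loss of epithelial cells with all other cell types in proportion stays open. The mesenchyme median exceeded that of 57 other non-epithelial markers by 0.94 (95% bootstrap interval over genes 0.62 to 1.27). A first version with 7 neural crest genes gave 1.55 (0.20 to 3.11). The 57 markers were not shown to mark cells present here, and some are liver genes raised in wild type replicate 2. The interval also treats genes as independent and leaves out the spread between libraries. A mixture of cells that varies between libraries stays open. The lists moved apart beyond random lists in 3 of 6 within-group pairs and together in 1. Random lists held unrelated genes, whereas the epithelial and mesenchyme lists had estimated correlations of 0.497 and 0.225. Lists of correlated genes can pass random lists more easily, and the pairs within a group depend on each other, so these counts decide nothing. Earlier, 2 forms of this test, on knockout replicate 2 minus 1 alone, had come out in favour of a mixture. An effect of the genotype and one of the single clone or culture cannot be separated by this design.

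Mitochondrially encoded transcripts were low in knockout replicate 3, where all 13 lay below both other knockout libraries, with a median log2 difference of -1.29. The other genes had a median of 0.0206, so the fall was not shared by the typical gene. FPKM is already divided by the library's mapped fragments, so this median cannot test whether the whole library was scaled down. Lower nuclear transcripts of the respiratory chain are argued against, since 79 such genes had a median of 0.0399. RNA handling and mitochondrial content were not tested.

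In wild type replicate 2, 12 of 16 endoderm and liver genes were over 2-fold above both other wild type libraries on the FPKM + 1 scale, including APOA1 at 75.1 FPKM against 14.2 and 8.89. The median of all genes was -0.10, so the rise was not shared by the typical gene. Since FPKM is already divided by mapped fragments, a scaled-up library could not be tested this way. Cells of a liver or yolk sac type may be present, but this stays open. The outcome depends on the pseudocount and on which genes count as measured. Of 12 measured genes of a second list, 4 (33.3%) were over 2-fold above both on the FPKM + 1 scale. In FPKM, 8 (66.7%) were. The shares of all tested genes, which were kept by their mean over the 6 libraries, were 0.861% and 1.68%. Measured meant at least 1 FPKM in any wild type library, which let in genes that reached it in replicate 2 alone. Of the 4 second-list genes that reached 1 FPKM in wild type replicate 1 or 3, 1 was over 2-fold above both on either scale. APOA4 was at 49.2 FPKM against 1.66 and 0.469, while ALB, albumin, was at 1.19 against 0.214 and 0.0961.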
